A study of Mus musculus with 6 samples.

How the data were processed

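RNA of HSCs (hematopoietic stem cells) and of MPPs (multipotent progenitors) from mice was measured on 6 dual-colour Agilent oligonucleotide arrays. Per the labels, both populations were purified by FACS from C57BL6 mice 2 to 3 months old, and total RNA was isolated with Trizol. The labels also give 10 µg of total RNA per sample, labelled directly by reverse transcription with a T16N2 primer and SuperScript II. Each array held 1 Bmi1 KO sample in red (Cy5) against 1 wild-type (WT) sample in green (Cy3). There were 3 HSC and 3 MPP arrays, all on 1 slide and from 1 scan, and the labels call the replicates biological. All HSC arrays and MPP replicate 1 lay in row 1 of the slide and MPP replicates 2 and 3 in row 2. Row was thus partly confounded with population. No array had the dyes exchanged, so in the ratios a dye effect specific to a probe has the same direction as genotype. Such an effect cancels in the difference between the populations and in comparisons within 1 dye.

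Per the file headers, each array's file held the intensity of every spot and of its local background in both channels, read from the scans with Agilent Feature Extraction 10.7.3.1. The submitters' processing notes name version 8.5.1.1, and which version was used was not settled here. The deposited processed intensity had been background-subtracted, detrended and dye-normalized within each array by that software. The deposited log ratio was a log10 of processed red over processed green, and the series table held that same log10 value for all 6 arrays. The other columns used here were deposited as 0 or 1 marks for spots well above background, saturated, non-uniform or outlying. Each array carried 62976 spots, of which 3671 were controls and 59305 measured 55681 probes. Probe positions were those in the files, on mouse assembly mm9. RefSeq accessions gave current symbols to 27235 probes (48.9%), and the other probes kept the name in the file.

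Mean spot intensities were corrected for local background with the normexp method of limma 3.58.1 (R 4.3.3, offset 50), and log2 ratios of KO over WT were loess-normalized within each array. Control spots and spots marked non-uniform or outlying in either channel had weight 0 in the loess curve. The values of these marked spots were then left out, and the other spots of the same probe were averaged. A probe was kept when it was well above background in all 3 arrays of at least 1 of the 4 groups. It also needed a value on all 6 arrays, which left 44639 probes. Where a name had several probes, the probe with the highest mean intensity was taken, which gave 29133 features. Channel levels were log2 background-corrected signals, quantile-normalized between the 6 arrays within each dye. These levels were not compared between dyes to test genotype. Where a range of levels below spans both dyes, the split it shows also held within each dye. Files were read with the R packages jsonlite 2.0.0 and data.table (version 1.17.8).

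Features were tested with limma (lmFit and eBayes) on all 6 arrays with 1 mean per population, and p-values were adjusted by the Benjamini-Hochberg method over features with a threshold of 0.05. The shared spread gave the ratios 6.43 total degrees of freedom. The Cy3 and Cy5 channels had 6.29 and 6.64. The comparisons were KO against WT in HSCs, the same in MPPs, the MPP effect minus the HSC effect, the mean effect over both, and MPPs against HSCs within the WT and within the KO channel. These p-values measure the spread between the samples at hand. A sign-flip permutation of 3 arrays cannot give a two-sided p below 0.25. Values are log2 with the model's standard error (SE), from 3 arrays per population.

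The 30 gene lists, the filter, the tests, the other settings to be tried and the rule for naming genes were fixed before the data were examined. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's genes move, on balance, one way and does not compare the list with other genes. Each list also has a count of members passing when adjusted over the list alone. Genes were named by rule. Bmi1, Cdkn2a and Cdkn2b were always named. Up to 12 passing genes per direction with the largest change were named, provided every array had the same sign, or the groups did not overlap for a single dye. Where fewer than 5 passed in a direction, the 5 with the smallest p and a consistent sign were named. Of each list, the 2 to 4 members with the smallest p could be named. RIKEN clones, predicted genes and names that are only accessions were counted but not named.

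The pipeline was tested on simulated data with 200 shifted features. In the MPP comparison 27.5% were recovered at a 4-fold change and 77.0% at 16-fold. In the HSC comparison these shares were 25.5% and 73.5%, for the mean effect 50.5% and 90.0%, and for the difference of effects 0% and 53.5%. Within the WT channel 0% and 76.5% were recovered, and within the KO channel 34.0% and 79.5%. None of the 200 was recovered at 2-fold in any comparison. False calls numbered 0 to 5 at 4-fold and 4 to 18 at 16-fold. At 16-fold there were 18 beside 180 right calls for the mean effect and 15 beside 154 in MPPs, and at 4-fold 4 beside 55 in MPPs, each a larger share than the threshold of 0.05. A list with 15 members shifted by 1 log2 was called in all 6 comparisons, with 0 other lists called. The simulated features varied independently, so this does not show how often lists of correlated genes are called falsely.

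Alternatives covered background subtraction, normalization, the series table, the filter, several probes per gene, limma's trend and robust options, a separate-channel model, a replicate block, the array row on the slide and leaving out each array. Array weights and leaving out both arrays of replicate 2 or of replicate 3 were chosen after seeing the data. Replicate numbers were not treated as pairing HSC with MPP arrays. The spike-in spots were not used for normalization, and no reference genome was used.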

Results

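Gene expression was compared between Bmi1 KO and WT mice in HSCs, the cells that maintain blood formation for life, and in MPPs, their first descendants. Bmi1 encodes a subunit of Polycomb repressive complex 1 (PRC1) that represses the Ink4a-Arf locus. Each of the 6 arrays set 1 KO-labelled sample (red, Cy5) against 1 WT sample (green, Cy3), with 3 arrays per population. The median spot signal was 200, 140 and 140 in green and 581, 379 and 477 in red on HSC replicates 1, 2 and 3. On MPP replicates 1, 2 and 3 it was 206, 124 and 135 in green and 501, 462 and 463 in red. Between 72.5% and 82.2% of spots were well above background in green and between 78.8% and 83.9% in red. Among the 59305 spots that were not controls, 1 was saturated on HSC 2, 1 on MPP 2 and 0 on the other arrays. The number of arrays limits the precision of every value. Log2 ratios of replicate arrays hardly correlated across features, with r from -0.0764 to 0.0855 within HSCs and from -0.0141 to 0.219 within MPPs. Over all pairs of arrays, WT channels correlated at 0.813 to 0.935 and KO channels at 0.869 to 0.969. Within HSCs r was 0.860 to 0.888 in WT and 0.891 to 0.922 in KO. Within MPPs it was 0.917 to 0.935 in WT and 0.950 to 0.969 in KO. Between populations it was 0.813 to 0.922 in WT and 0.869 to 0.937 in KO, so some HSC arrays correlated better with an MPP array than with each other.

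The labels do not say which part of Bmi1 the KO allele lacks, so a probe outside that part checks nothing, and the KO status is taken from the labels. The Bmi1 probe with the higher signal (A_55_P2170335, chromosome 2, 18607531 to 18607590, mm9) had a log2 KO/WT ratio of -1.11 ± 1.14 (SD, n = 3) in HSCs and 0.01 ± 0.62 (SD, n = 3) in MPPs. It was lower in the KO channel on 4 of 6 arrays, and its KO signal was well above background on all 6. In HSCs it was -0.45 without HSC 2. In MPPs its sign changed without MPP 1 (-0.10) or MPP 3 (-0.23), and it was 0.35 without MPP 2. A second Bmi1 probe (18607987 to 18608046) gave -0.06 ± 1.52 in HSCs and 0.53 ± 0.52 in MPPs. Cdkn2a, which encodes the cell cycle inhibitor p16Ink4a and p19Arf (chromosome 4, 88920405 to 88920464), had ratios of -0.95 (SE 0.60) in HSCs and 1.18 (SE 0.60) in MPPs, and was higher in the KO channel of 3 of 3 MPP arrays and of 1 of 3 HSC arrays. In HSCs that probe gave -0.01 without HSC 3 and -1.57 without HSC 1. A second Cdkn2a probe had no WT signal well above background on the MPP arrays, so no ratio is given for it. Cdkn2b, which encodes p15Ink4b (88952720 to 88952779), had ratios of 0.79 (SE 0.62) in HSCs and 0.62 (SE 0.62) in MPPs. The HSC value rests on 1 array: Cdkn2b was not well above background in WT on any HSC array, nor in KO on HSC 2 and HSC 3, and the value was -0.26 without HSC 1, 1.28 without HSC 2 and 1.34 without HSC 3. None of these genes passed the limma test, with adjusted p of 0.664, 0.719 and 0.751 in HSCs and of 1.00, 0.965 and 0.984 in MPPs.

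**Figure D1:**
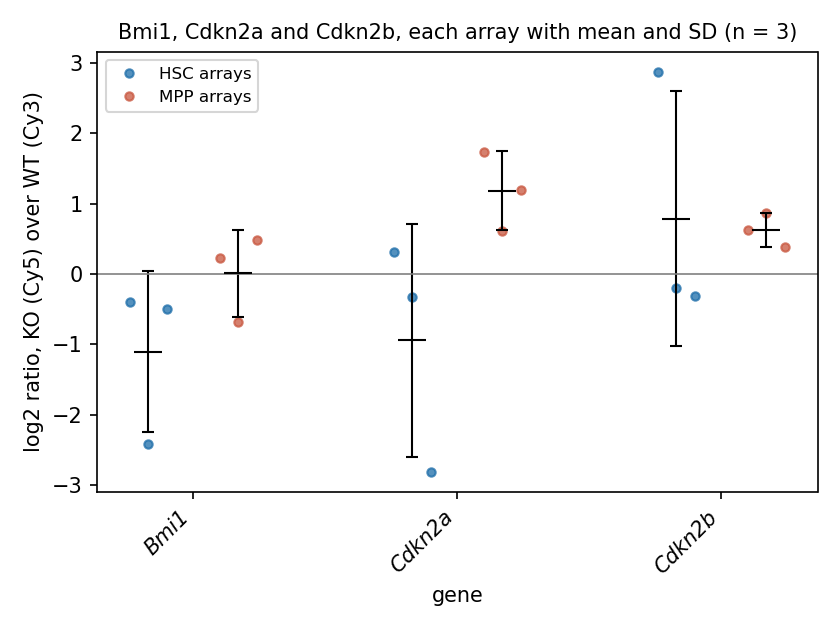
Log2 ratio of KO (Cy5) over WT (Cy3) for Bmi1, Cdkn2a and Cdkn2b on each of the 6 arrays (y axis, log2), with the mean and SD of 3 arrays; HSC and MPP arrays have separate colours. Cdkn2a lies above 0 on 3 of 3 MPP arrays, while the Cdkn2b mean in HSCs rests on HSC 1 at 2.88.

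In HSCs, immediate early genes, which are transcribed within minutes of a stimulus, were higher in the KO channel as a group. Of 17 measured members 16 had a positive mean ratio and the median was 0.53. Egr2, a zinc finger transcription factor, had a ratio of 1.76 (SE 0.31). It was the 1 member passing when adjusted over the list alone, against 0 over all features. Fos, an AP-1 subunit, had 1.29 (SE 0.42), Atf3, a stress-response transcription factor, 3.55 (SE 1.38), and Klf6, a zinc finger factor, 1.66 (SE 0.72). The list rose by camera (adjusted p = 0.00212) but not with an estimated correlation (adjusted p = 0.878 with an estimated correlation). Its array medians were 0.79, 1.88 and -0.34, so it was positive on 2 of 3 arrays. Without HSC 1 the median was 0.76 (adjusted p = 0.106), without HSC 2 it was 0.30 (adjusted p = 0.284) and without HSC 3 it was 1.32. Over all alternatives the adjusted p ran from 8.38e-11 to 0.896.

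No single feature passed in HSCs. The genes with the smallest p and a consistent sign included Phf10, a subunit of the PBAF chromatin remodelling complex, at 2.26 (SE 0.23). Also named were Npas2, a circadian transcription factor, at 2.52 (SE 0.35), Mrpl3, a mitochondrial ribosomal protein, at 1.97 (SE 0.25), and the imprinted gene Zdbf2 at 1.96 (SE 0.24). On the lower side stood Gcn1, an activator of the eIF2α kinase Gcn2, at -2.30 (SE 0.32), Pea15a, an ERK-binding protein, at -2.02 (SE 0.34), and Uqcr10, a subunit of respiratory complex III, at -1.97 (SE 0.33). Stxbp5, a regulator of vesicle fusion, stood at -1.90 (SE 0.31) and Psmg3, a proteasome assembly chaperone, at -1.46 (SE 0.22). Adjusted p was 0.570 for Phf10 and 0.652 for the other 8 of these.

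Among Polycomb subunits, 12 of 26 measured members had a positive ratio in HSCs. Pcgf2, a close paralogue of Bmi1, was 2.83-fold higher (its other probe -0.27) and Pcgf1, another PRC1 subunit, stood at -2.10 (SE 0.49), both with an adjusted p of 0.652. Within the Ink4 family, Cdkn2c was at least 1.55-fold higher, with KO signal well above background on 2 of 3 arrays, and Cdkn2d stood at -2.09 (SE 0.95). Among p53 targets, Ckap2, a spindle protein, stood at -2.80 (SE 0.87) and Ei24 at 1.39 (SE 0.52). Among HSC markers, Vwf, the platelet adhesion factor, stood at 1.47 (SE 0.38; its other probe -0.83) and Pdzk1ip1 at -0.58 (SE 0.28), which was 0.04 as a mean of its probes. Hoxa7 and Hoxb5 stood at 0.70 and -0.93.

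With limma 0 of 29133 features passed in HSCs (smallest adjusted p = 0.570) and 0 passed with the separate-channel model. At unadjusted p under 0.05 there were 2156 features, 1151 higher and 1005 lower in KO, where chance gives 1456.65 on average. With the signs of HSC 2 and HSC 3 reversed there were 2783, so the excess is not particular to the labels. The ratio had the same sign on all 3 arrays for 26.9% of features, where chance gives 25%. Scaling each array by its median in place of the loess curve moved the median of all features by 0.29 in HSCs and 0.26 in MPPs, so every ratio is relative to an intensity-dependent centre. Under that scaling the median of the immediate early genes was 1.49. The other 29 lists did not pass, with adjusted p of 0.0653 or more and medians from -0.39 to 0.51. Median, mean and test differed in sign for the erythroid, G2 and M phase, p53 and sex-linked lists.

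In MPPs, genes of the B cell lineage were higher in the KO channel by up to 36.8-fold. Ebf1, an early B cell transcription factor, had a log2 ratio of 5.20 (SE 0.65, 36.8-fold), and Pax5, which commits progenitors to the B lineage, 3.91 (SE 0.46, 15.1-fold; its other probe 1.90). Igll1, a component of the surrogate light chain of the pre-B cell receptor, had 4.03 (SE 0.57, 16.3-fold). Of 15 measured members 13 had a positive ratio, and 8 passed when adjusted over the list alone; 0 passed over all features (adjusted p = 0.695 for Pax5 and Ebf1 and 0.959 for Igll1). The list rose by camera with a median of 1.48 and a mean of 1.95 (adjusted p = 8.64e-12), but not with an estimated correlation (adjusted p = 0.595 with an estimated correlation). Array medians were 0.45, 2.11 and 2.24 in MPPs and 0.15, -0.11 and -0.42 in HSCs. Fry gave an adjusted p of 0.317 for movement one way and of 0.0343 for movement in either direction. Markers of other cells in the same comparison were not called: the erythroid list had a median of 0.39 (adjusted p = 0.105) and the basophil list -0.32 (adjusted p = 0.188).

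**Figure D2:**
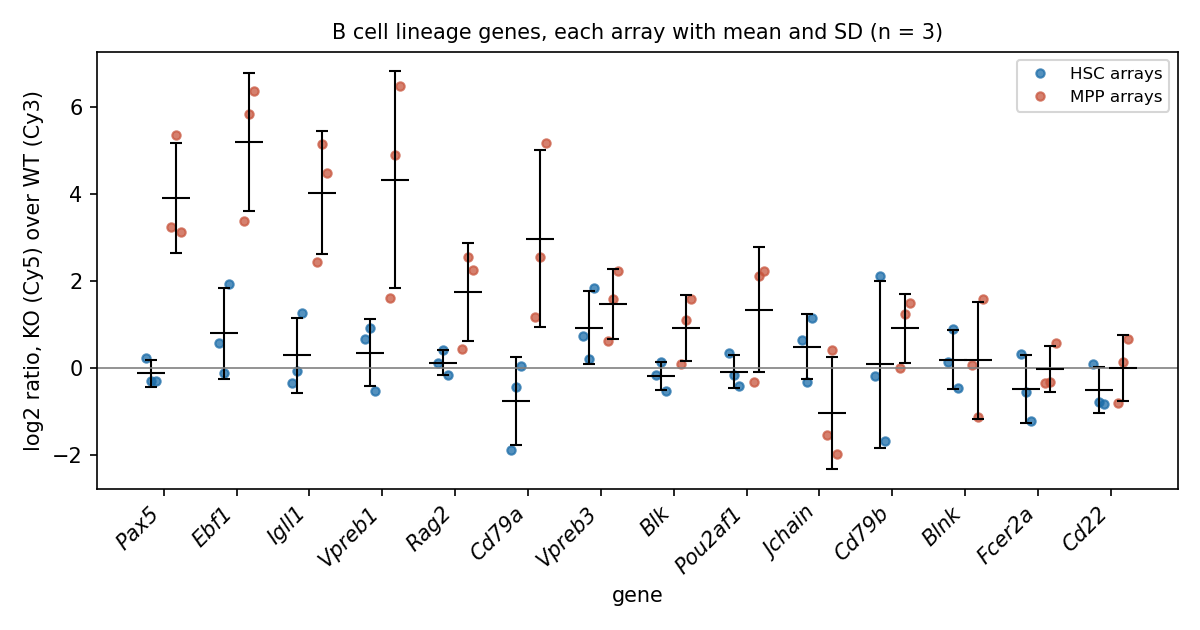
Log2 ratio of KO (Cy5) over WT (Cy3) for 14 of the 15 measured B lineage genes on each array (y axis, log2; x axis, genes), with the mean and SD of 3 arrays per population. Pax5, Ebf1, Igll1 and Vpreb1 lie above 0 on 3 of 3 MPP arrays, while their HSC arrays lie nearer to 0.

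Ribosome biogenesis genes also rose as a list in KO MPPs, with 44 of 59 measured members positive and a median of 0.24 (adjusted p = 0.00478; adjusted p = 0.595 with an estimated correlation). Ubtf, an RNA polymerase I factor, had 1.39 (SE 0.40; its other probe -0.48), Npm1, a nucleolar chaperone, 1.11 (SE 0.40), Heatr1, a processome component, 1.03 (SE 0.41), and nucleolin, Ncl, 0.89 (SE 0.28); 0 members passed over the list alone. Array medians were 0.29, 0.35 and 0.30, but without MPP 1 the list did not pass (median 0.29, adjusted p = 0.0838). Immediate early genes rose too, with 13 of 17 positive and a median of 0.52 (adjusted p = 0.0305; adjusted p = 0.760 with an estimated correlation). Klf2 had 2.28 (SE 0.77), Klf6 1.67 (SE 0.72), Fos 1.36 (SE 0.42) and Egr2 0.68 (SE 0.31), and 0 passed over the list alone. Its array medians were 1.08, 0.61 and -0.18, and the list did not pass without MPP 1 (median 0.41, adjusted p = 0.954) or with the Agilent log ratio (median 0.66, adjusted p = 0.0515), in a range of adjusted p from 9.52e-08 to 0.954. With median centring the medians of these lists were 0.58 and 0.86, against a shift of all features of 0.26.

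Outside these lists, Rnf113a1, an ubiquitin ligase on chromosome X, stood at 1.79 (SE 0.25) in KO MPPs. On the lower side were Ppard, a nuclear receptor for fatty acids, at -2.17 (SE 0.39), Wtap, a subunit of the m6A RNA methyltransferase, at -2.08 (SE 0.36; its probes from -2.08 to 0.50), Fbrs at -1.97 (SE 0.33), Kdm2a, a histone H3 demethylase, at -1.79 (SE 0.33) and Tmbim4 at -1.45 (SE 0.26). Among p53 targets Pmaip1, which encodes the apoptosis inducer Noxa, stood at 2.11 (SE 0.54). The PRC1 subunits Phc1 and Phc2 stood at -1.57 (SE 0.56) and 0.84 (SE 0.41); as a mean of its probes Phc2 was -0.05. The HSC markers Tek and Gata2 stood at -1.30 (SE 0.56) and -0.65 (SE 0.32), Hoxc10 and Hoxb6 at 1.96 (SE 0.76) and 1.77 (SE 0.70), and Cdkn2c at 0.57 (SE 0.32). All had an adjusted p of 0.959 or 0.965.

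With limma 0 features passed in MPPs (smallest adjusted p = 0.695), and 0 passed with the separate-channel model. At unadjusted p under 0.05 there were 1487, 725 higher and 762 lower in KO, where chance gives 1456.65, and 29.0% had the same sign on all 3 arrays. Of MPP and lymphoid markers 1 passed higher when adjusted over its list alone. The other 27 lists had adjusted p of 0.0964 or more and medians from -0.32 to 0.62. The Ink4 list (Cdkn2a, Cdkn2b, Cdkn2c, Cdkn2d and Mtap), all 5 members positive at a median of 0.62, was among them (adjusted p = 0.0964). So were HSC markers, 8 of 29 positive at a median of -0.29 (adjusted p = 0.0964). Median, mean and test differed in sign for the stromal, p53, monocyte and chromosome 2 neighbour lists.

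The difference between the effects asked whether KO cells departed from WT cells differently in MPPs and in HSCs; a constant dye effect cancels in it. B lineage genes had the larger KO ratio in MPPs: the difference was 4.41 (SE 0.92) for Ebf1, 4.04 (SE 0.66) for Pax5 and 3.74 (SE 0.81) for Igll1. Of 15 members 13 were positive, with a median of 1.43, and 6 passed when adjusted over the list alone against 0 over all features. The list passed by camera (adjusted p = 1.04e-08; adjusted p = 0.924 with an estimated correlation). Without MPP 1 the median was 2.26, and without both arrays of replicate 3 it was 0.81. Markers of basophils, mast cells and eosinophils went the other way, with 2 of 11 positive and a median of -0.96 (adjusted p = 0.0330; adjusted p = 0.924 with an estimated correlation). Ear1, an eosinophil ribonuclease, stood at -3.03 (SE 1.27), Mcpt8, a basophil protease, at -2.95 (SE 1.06), Epx, eosinophil peroxidase, at -2.33 (SE 0.98) and Prg2, major basic protein, at -1.42 (SE 0.93); 0 passed over the list alone. The basophil call was lost without HSC 3 (median -0.44, adjusted p = 0.354), without MPP 3 (median -0.37, adjusted p = 0.512) and with median centring (median -0.50, adjusted p = 0.343), in a range from 0.00276 to 0.969. Its array medians were 0.03, 0.04 and 1.56 in HSCs and 0.41, -0.37 and -1.02 in MPPs.

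Among single genes the smallest p belonged to Phf10 at -2.81 (SE 0.32) and Psmg3 at 2.23 (SE 0.30). Hyou1, an ER chaperone, stood at 2.67 (SE 0.44), Gcn1 at 2.54 (SE 0.45), Rab3a, a vesicle GTPase, at -3.10 (SE 0.49), Urgcp at -4.70 (SE 0.76; its other probe -0.72) and Scamp1, a vesicle membrane protein, at -2.26 (SE 0.41; its other probe -0.04). Cdkn2a stood at 2.13 (SE 0.85; 1.19 without HSC 3), Bmi1 at 1.11 (SE 0.66; 0.45 without HSC 2) and Cdkn2d at 3.46 (SE 1.34). No difference is given as an estimate for Cdkn2b, whose only HSC signal well above background was in KO on HSC 1. Pcgf1 and Pcgf2 stood at 2.79 (SE 0.69) and -1.62 (SE 0.47), Ckap2 and Ei24 at 3.21 (SE 1.24) and -2.39 (SE 0.74), and Vwf, Hoxb5 and Hoxc11 at -1.76 (SE 0.53), 1.78 (SE 0.80) and -0.59 (SE 0.32). Each had an adjusted p of 0.964, and Cdkn2b one of 0.996. With limma 0 features passed, and 0 with the separate-channel model; 1175 had an unadjusted p under 0.05 (490 higher, 685 lower), and HSC and MPP ratios did not overlap for 8.10%, where chance gives 10%. The other 28 lists had adjusted p of 0.227 or more and medians from -0.54 to 0.48. Median, mean and test differed in sign for ribosome biogenesis, oxidative phosphorylation, T and NK cells, the unfolded protein response, Hox, megakaryocyte and sex-linked genes.

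The mean effect averaged the KO effects in HSCs and MPPs, so a change in 1 population alone can carry it. Lin28b, an RNA-binding protein that blocks let-7 microRNAs and marks fetal HSCs (chromosome 10, 45140412 to 45140471), was higher in the KO channel on 6 of 6 arrays. Its WT signal was well above background on 1 of 6 arrays only, so no size is given. Immediate early genes had 13 of 17 members positive at a median of 0.67, and 2 passed over the list alone: the values were 3.23 (SE 0.98) for Atf3, 1.66 (SE 0.51) for Klf6, 1.32 (SE 0.30) for Fos and 1.22 (SE 0.22) for Egr2. The list rose (adjusted p = 4.44e-04; adjusted p = 0.722 with an estimated correlation), though not without MPP 1 (median 0.52, adjusted p = 0.236), and its median was 1.04 without MPP 3; over all alternatives adjusted p ran from 1.78e-12 to 0.726. Ribosome biogenesis genes rose by a median of 0.26, with 43 of 59 positive and 0 passing over the list alone (adjusted p = 7.65e-04; adjusted p = 0.722 with an estimated correlation). Rrs1, a ribosome assembly factor, had 1.55 (SE 0.45), Ubtf 1.18 (SE 0.28), Mrto4 1.02 (SE 0.20; its other probe -0.53) and Npm1 0.96 (SE 0.28). The B lineage list also passed, carried by MPPs, as its HSC median was 0.08 (adjusted p = 0.970). Its mean effect had a median of 0.94 with 12 of 15 positive and 7 passing over the list alone (adjusted p = 8.75e-06; adjusted p = 0.722 with an estimated correlation), and the median was 0.56 without MPP 3. Ebf1 had 3.00 (SE 0.46), Igll1 2.16 (SE 0.40) and Pax5 1.89 (SE 0.33).

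S phase genes rose in the mean effect by a median of 0.26, with 32 of 44 positive and 0 passing over the list alone (adjusted p = 0.0221; adjusted p = 0.722 with an estimated correlation). Prim1, a DNA primase subunit, had 1.30 (SE 0.43), Tipin, a replication fork protein, 1.19 (SE 0.50), Ccne1, cyclin E1, 0.94 (SE 0.29; its other probe -1.67) and Ung, a uracil DNA glycosylase, 0.66 (SE 0.25). This list did not pass without HSC 3 (median 0.05, adjusted p = 0.518), without MPP 1 (0.26, adjusted p = 0.224) or with median centring (0.60, adjusted p = 0.126), in a range from 0.00216 to 0.726, and its median was 0.40 without HSC 2. Heat shock and chaperone genes rose by a median of 0.30, with 17 of 21 positive and 0 passing over the list alone (adjusted p = 0.0494; adjusted p = 0.722 with an estimated correlation). Hsf1, the heat shock transcription factor, had 0.71 (SE 0.23), Cct5, a chaperonin subunit, 0.65 (SE 0.22), Hspa8, a constitutive Hsp70, 0.63 (SE 0.25) and Hspa4 -0.41 (SE 0.15), which turned to 0.42 with the Agilent log ratio and 0.10 with median centring. That call was lost without HSC 2 (median 0.19, adjusted p = 0.348), HSC 3 (0.33, adjusted p = 0.0582) or MPP 1 (0.40, adjusted p = 0.236) and without the filter (0.26, adjusted p = 0.0859), in a range from 0.00480 to 0.722.

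Other genes with the smallest p in the mean effect included Mrpl3 at 1.33 (SE 0.18), Rnf113a1 at 1.25 (SE 0.18) and Zdbf2 at 1.17 (SE 0.17). On the lower side stood Tmem134, 3.99-fold lower, Ncald, a neuronal calcium sensor, at -1.61 (SE 0.27), Pea15a at -1.43 (SE 0.24), the homeobox gene Rhox3a at -1.10 (SE 0.15) and Syn3, a synapsin, at -1.07 (SE 0.17; its other probe -0.01). Gadd45a and Pmaip1, both p53 targets, stood at 1.70 (SE 0.63) and 1.11 (SE 0.38), Pcgf2 and Phc1 at 0.69 (SE 0.23) and -1.17 (SE 0.40), Hoxc10 and Hoxb6 at 1.32 (SE 0.54) and 1.21 (SE 0.50), and the HSC genes Tek and Gfi1b at -1.11 (SE 0.40) and -0.56 (SE 0.25). No mean effect is given for Cdkn2b and Cdkn2c, which were not well above background in WT HSCs. Bmi1 stood at -0.55 (SE 0.33), which was -0.22 without HSC 2 and -0.05 without both arrays of replicate 2, and Cdkn2a at 0.12 (SE 0.42), which was -0.20 without HSC 1, -0.04 without HSC 2, -0.02 without MPP 1 and 0.59 without HSC 3. With limma 0 features passed (smallest adjusted p = 0.567), and 0 with the separate-channel model; 2438 had an unadjusted p under 0.05, 1308 higher and 1130 lower. With median centring 303 features passed, 299 higher and 4 lower, where the median of all features had moved by 0.28 and those of the immediate early, ribosome biogenesis and heat shock lists were 1.30, 0.65 and 0.84. The same sign on all 6 arrays was found for 6.56%, where chance gives 3.125%. The other 25 lists had adjusted p of 0.198 or more and medians from -0.21 to 0.25; median, mean and test differed in sign for ribosomal protein, Hox, MPP marker, monocyte and p53 genes.

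Across the 29133 features, which are not independent replicates, HSC and MPP ratios correlated with a Pearson r of 0.111 and a Spearman rho of 0.144. At unadjusted p under 0.05, 124 features were higher in KO in both populations where chance gives 28.6, and 71 were lower in both where chance gives 26.3. The dyes lay the same way round in both populations, and both tests used the same estimate of each feature's spread. A small spread favours a low p in both, so the excess does not measure a shared KO effect. Pearson r was 0.0608 without HSC 1, 0.0591 without MPP 1 and 0.278 with median centring.

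Within the WT channel, some genes used to mark these populations differed between MPPs and HSCs. Flt3, the cytokine receptor whose appearance marks MPPs, was higher in WT MPPs by 3.03 (SE 0.28, 8.16-fold, adjusted p = 0.0230; its probes from 0.44 to 4.34), Dntt, the lymphoid DNA polymerase TdT, by 2.76 (SE 0.33, adjusted p = 0.0389), and Rag2, a V(D)J recombinase subunit, by at least 7.57-fold (adjusted p = 0.0162; its other probe 0.03). The chemokine Ccl9 rose by 5.81 (SE 0.30, 56.1-fold, adjusted p = 0.00580). Other genes that rose were Ubash3a by 5.50, Tmem150b by 4.93 (its other probe -0.64), the IL-1 receptor Il1r1 by 4.72, Bex6 by 4.55, F13a1 by 4.17, the MHC class II chain H2-Ab1 by 3.94, the tetraspanin Cd53 by 3.92, the cystatin Cst7 by 3.85, Polg2 by 3.81 and Tespa1 by 3.75, with SE from 0.28 to 0.57. Among genes that fell in WT MPPs were Nrbp2 at -4.87 (SE 0.31, adjusted p = 0.0122), Clca3a2 at -3.91, Nupr1, a stress-induced chromatin protein, at -3.82, the RNA-binding protein Igf2bp2 at -3.75, the transglutaminase Tgm2 at -3.37 and Slc6a15 at -3.21. Pde9a fell by 3.15, the cytokine signalling inhibitor Cish by 3.11, Notch3 by 2.98, Sytl5 by at least 6.32-fold and Sult1a1 by 2.84. As a mean of probes Tmem150b (2.14, adjusted p = 0.274) and Rag2 (1.56, adjusted p = 0.0531) lost their calls. With processed signal scaled by the 75th percentile, so did Il1r1 (7.27, adjusted p = 0.108), F13a1 (7.25, adjusted p = 0.0839), Polg2 (6.30, adjusted p = 0.205), Notch3 (-4.47, adjusted p = 0.114) and Slc6a15 (-6.29, adjusted p = 0.104), while Rag2 (6.60), Cish (-5.76) and Sytl5 (-7.04) still passed. Bmi1, Cdkn2a and Cdkn2b stood at 0.45 (SE 0.46), -0.83 (SE 0.81) and at least 1.07-fold higher (well above background on 2 of 3 WT MPP arrays), and did not pass (adjusted p = 0.658, 0.645 and 0.853). The Bmi1 value was 0.15 without MPP 2, 0.85 without HSC 3 and -0.02 without replicate 2, and the Cdkn2a value was 0.14 without HSC 3 and -1.40 without HSC 1.

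As lists, MPP and lymphoid-primed markers rose in WT MPPs by a median of 1.84, with 14 of 15 positive, 3 passing over all features and 10 adjusted over the list alone (adjusted p = 1.48e-10; adjusted p = 0.123 with an estimated correlation). HSC markers fell by 1.13, with 1 of 29 positive, 0 passing over all features and 15 over the list alone (adjusted p = 8.46e-10; adjusted p = 0.123 with an estimated correlation). Among them Mllt3, a regulator of HSC self-renewal, stood at -2.32 (SE 0.48), Clca3a1 at -1.63 (SE 0.34) and Gata2 at -1.50 (SE 0.31). Cell cycle genes rose: the G2 and M phase list by a median of 0.84 with 44 of 51 positive and 7 passing over the list alone (adjusted p = 8.46e-10; adjusted p = 0.145 with an estimated correlation), and the S phase list by 1.09 with 39 of 44 positive and 2 over the list alone (adjusted p = 2.35e-09; adjusted p = 0.123 with an estimated correlation). The helicase Hells stood at 3.19, the mitotic genes Ect2 and Kif11 at 2.62 and 2.17, and the replication licensing factor Cdc6 at 2.22 (its other probe -0.06).

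Growth and protein synthesis genes rose alongside in WT MPPs. Oxidative phosphorylation genes rose by a median of 0.57, with 58 of 72 positive (adjusted p = 4.69e-05; adjusted p = 0.199 with an estimated correlation), among them Atp5o at 2.76 and Ndufs4 at 2.14. MYC, one-carbon and nucleotide synthesis genes rose by 0.83, with 21 of 27 positive (adjusted p = 2.12e-04; adjusted p = 0.189 with an estimated correlation), among them Umps at 2.49 and Mthfd2 at 2.15. Without HSC 2 these medians were 0.25 and 0.53. Ribosome biogenesis genes rose by 0.43, with 44 of 59 positive and 1 passing over the list alone (adjusted p = 1.22e-04; adjusted p = 0.123 with an estimated correlation). Rrs1 stood at 2.61 and Nop58 at 1.60. Proteasome subunits rose by 0.39, with 31 of 38 positive and 4 over the list alone (adjusted p = 7.65e-04; adjusted p = 0.179 with an estimated correlation). Psmd13 was 8.56-fold higher and Psma5 stood at 2.53. Translation factors rose by 0.22, with 30 of 42 positive (adjusted p = 0.00238; adjusted p = 0.248 with an estimated correlation), although Eif6 stood at -1.25 beside Eif1a at 1.59. Their median was 0.13 without HSC 2, 0.41 without HSC 3 and 0.43 without MPP 1. Ribosomal proteins rose by 0.24, with 65 of 80 positive (adjusted p = 0.00238; adjusted p = 0.522 with an estimated correlation), among them Rps27l at 1.54 and Rps10 at 0.66. Their median was 0.47 without MPP 1, and the call ended without MPP 3 (0.06, adjusted p = 0.206, in a range from 1.85e-07 to 0.522). Polycomb subunits rose by 0.53, with 19 of 26 positive (adjusted p = 0.0161; adjusted p = 0.179 with an estimated correlation), with Pcgf6 at 1.45 and Ezh1, a histone H3K27 methyltransferase, at -1.02. That call ended without HSC 2 (0.31, adjusted p = 0.0693, in a range from 0.00835 to 0.179). In the other 5 of these lists 0 members passed over the list alone.

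Markers of other blood cells moved in the WT channel together with these groups. Basophil, mast cell and eosinophil markers rose by a median of 2.07, with 9 of 11 positive and 5 over the list alone (adjusted p = 2.12e-04; adjusted p = 0.268 with an estimated correlation). Mcpt8 stood at 4.27 and the chemokine Ccl3 at 4.18. The median was 3.31 without MPP 2, 0.92 without MPP 3 and 3.73 with processed signal. Granulocyte markers rose by 0.70, with 13 of 19 positive (adjusted p = 0.0393; adjusted p = 0.479 with an estimated correlation), among them Mpo, myeloperoxidase, at 4.60 and Ctsg at 2.50. Their call ended without HSC 1 (0.24, adjusted p = 0.198), HSC 2 (0.31, adjusted p = 0.129) or MPP 1 (0.73, adjusted p = 0.0948), in a range from 2.33e-04 to 0.534. The median turned to -0.07 without MPP 3, and was 1.15 without HSC 3, 1.17 without MPP 2 and 1.15 with processed signal. Median levels of granulocyte markers were 10.2 on WT HSC 3 and 11.1 on WT MPP 3, against 6.61 to 7.57 on the other 4 WT samples. B lineage markers rose by 0.38, with 12 of 15 positive, 1 passing over all features and 2 over the list alone (adjusted p = 0.00238; adjusted p = 0.199 with an estimated correlation). Jchain, the immunoglobulin joining chain, stood at 5.29 (adjusted p = 0.0637), Cd79a at 2.23 and Ebf1 at 0.84, and the median was 0.21 without MPP 3. Megakaryocyte markers fell by 0.75, with 2 of 15 positive and 2 lower over the list alone (adjusted p = 0.00304; adjusted p = 0.179 with an estimated correlation). Mmrn1 stood at -3.59 (its other probe -0.99) and Tubb1 at -1.01. The median was -1.16 without HSC 3 and with processed signal and -0.47 without MPP 2. Stromal and endothelial markers fell by 0.64, with 1 of 10 positive and 1 lower over the list alone (adjusted p = 0.0290; adjusted p = 0.189 with an estimated correlation), among them Emcn at -1.27 and Kitl at -0.65. This call ended without HSC 1 (-0.50, adjusted p = 0.0758), HSC 3 (-0.50, adjusted p = 0.0710), MPP 1 (-0.51, adjusted p = 0.108) or the filter (-0.49, adjusted p = 0.0590), in a range from 0.0117 to 0.189. The p53 targets rose by 0.37, with 20 of 25 positive (adjusted p = 0.0393; adjusted p = 0.248 with an estimated correlation), among them Ei24 at 1.65 and Polk at 0.82. Their median was 0.64 without MPP 1 and 0.61 with processed signal. The call ended without HSC 1 (0.40, adjusted p = 0.188), HSC 2 (0.17, adjusted p = 0.140), MPP 2 (0.37, adjusted p = 0.0614) or MPP 3 (0.23, adjusted p = 0.115), in a range from 0.0139 to 0.248.

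With limma 122 features passed in the WT channel, 105 higher and 17 lower in MPPs, each by at least 2-fold, and 4418 had an unadjusted p under 0.05. The groups did not overlap for 22.1% of features, where chance gives 10%. The count rested on single arrays: it was 2 without HSC 1, 65 without HSC 2, 47 without HSC 3, 7 without MPP 1, 121 without MPP 2 and 0 without MPP 3, and of 26 named genes that passed, 0 passed in all 6 of these fits and Ccl9 in 4. Flt3 passed in 1 of these 6 fits, Rag2 in 2 and Dntt in 0. The count was 51 without the filter, 281 with the separate-channel model, and 0 with the array row or the replicate number in the model. The other 13 lists had adjusted p of 0.0578 or more and medians from -0.61 to 0.56. Median, mean and test differed in sign for the T and NK cell, immediate early and Ink4 lists.

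In the KO channel the same populations were separated by Dntt, higher in MPPs by 3.59 (SE 0.28, adjusted p = 0.00572), Flt3 by 2.92 (SE 0.29, adjusted p = 0.0145) and Satb1, a chromatin organizer of lymphoid progenitors, by 3.74 (SE 0.42, adjusted p = 0.0243). Rag2 was at least 44.6-fold higher (adjusted p = 0.00837; its other probe 0.61), and Pax5 rose by 4.40 (SE 0.51, 21.2-fold, adjusted p = 0.0276). HSC genes fell: Vwf by 3.35 (SE 0.33, adjusted p = 0.0144; its other probe -0.61), Cdkn1c, the quiescence-associated inhibitor p57Kip2, by 2.96 (SE 0.32, adjusted p = 0.0217), and Mllt3 by 2.94 (SE 0.36). Further rises were Bex6 by 5.46, Slc9a9 36.8-fold, Drc7 by 5.18, Tmem150b by 5.13 (other probe 0.51), Jchain by 4.49, the B cell surface protein Cd180 at least 16.5-fold, the urokinase gene Plau at least 13.3-fold, Tmem156 by 3.97, the MHC class II chain H2-DMb2 by 3.95 (SE 0.24, adjusted p = 0.00267) and the adaptor Grap by 3.93. Further falls were Clca3a2 at -5.05 (SE 0.64), the imprinted noncoding RNA Meg3 at -4.38 (SE 0.61), Evc2 at -4.05 (other probe -0.55), Grhl1 at -3.20, the actin bundler Fscn1 and Rassf6 at -3.18 each, Sult1a1 at -3.11, Timp3 at -3.05 and Tgfbr3 (adjusted p = 0.0205). Bmi1 stood at 1.67 (SE 0.74, adjusted p = 0.429), Cdkn2a at 1.58 (SE 0.33, adjusted p = 0.139) and Cdkn2b, in KO HSCs well above background on HSC 1 alone, at 0.20 (SE 1.03, adjusted p = 0.949), which was 1.45 without HSC 1, -0.42 without HSC 2 or HSC 3, -0.13 without MPP 2 and 0.52 without MPP 3. Bmi1 was 0.85 without HSC 2. As a mean of probes Tmem150b was 2.82, Evc2 -2.30 and Vwf -1.98, and with processed signal Cd180 was 7.68 and Plau 7.02, all still passing, while Grhl1 lost its call (-5.45, adjusted p = 0.104).

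**Figure D3:**
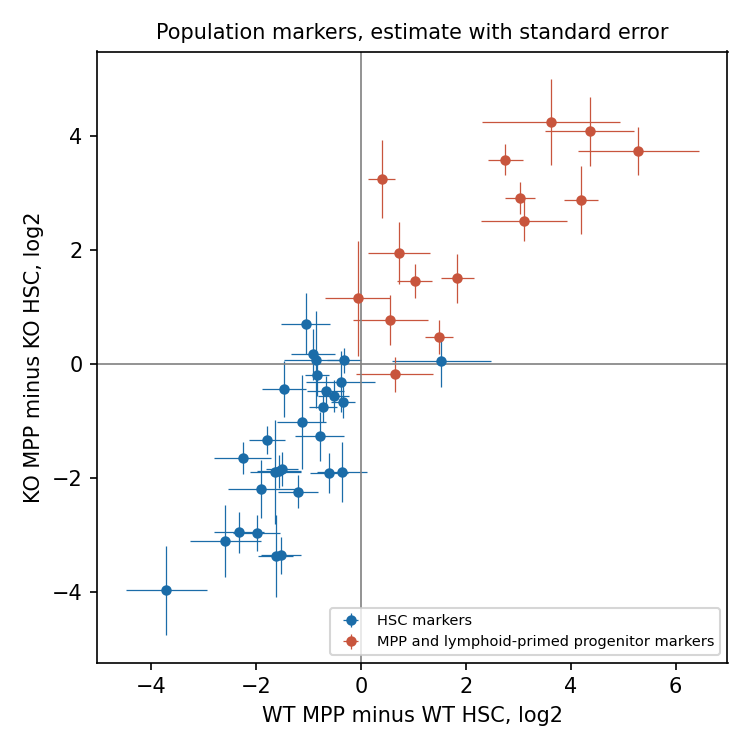
MPP minus HSC difference of each measured HSC marker and MPP or lymphoid marker in the WT channel (x axis, log2) and in the KO channel (y axis, log2), with standard errors; each point is 1 gene. MPP markers lie mostly to the upper right and HSC markers to the lower left, at medians of 1.84 and -1.13 in WT and 2.52 and -1.33 in KO.

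As lists, MPP and lymphoid markers rose in KO MPPs by a median of 2.52, with 14 of 15 positive, 4 passing over all features and 11 over the list alone (adjusted p = 1.64e-14). HSC markers fell by 1.33, with 5 of 29 positive, 4 lower over all features and 16 over the list alone (adjusted p = 8.52e-12). Both held with an estimated correlation (adjusted p = 0.0190 with an estimated correlation), and 0 other lists in the 6 comparisons did. Emb, another MPP gene, rose by 2.52 (adjusted p = 0.0499). G2 and M phase genes rose by 1.28, with 46 of 51 positive and 19 over the list alone (adjusted p = 1.77e-17; adjusted p = 0.114 with an estimated correlation). Ect2 rose by 2.18 (adjusted p = 0.0423), and Kif11 stood at 1.68. S phase genes rose by 1.04, with 40 of 44 positive and 4 over the list alone (adjusted p = 2.03e-11; adjusted p = 0.114 with an estimated correlation), among them Mcm5 at 1.95 and Brip1 at 1.04. B lineage markers rose by 4.14, with 13 of 15 positive, 3 passing over all features and 9 over the list alone (adjusted p = 3.97e-11; adjusted p = 0.114 with an estimated correlation). Ebf1 stood at 5.51 (SE 0.80, adjusted p = 0.0517), and the median was 1.99 without the filter. The Ink4 list, which includes Mtap, rose by 1.57, with 4 of 5 positive and 3 over the list alone (adjusted p = 0.00733, and adjusted p = 0.114 with an estimated correlation). Cdkn2c stood at 2.72 (SE 0.43, adjusted p = 0.0686), and the median was 0.93 without both arrays of replicate 3.

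MYC, one-carbon and nucleotide synthesis genes rose by 1.03 in KO MPPs, with 23 of 27 positive and, over the list alone, 7 higher and 1 lower (adjusted p = 4.09e-09; adjusted p = 0.0513 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose by 3.85 (SE 0.25, adjusted p = 0.00333) and the amino acid transporter Slc7a5 by 2.23 (SE 0.28, adjusted p = 0.0347). Ribosome biogenesis genes rose by 0.59, with 47 of 59 positive (adjusted p = 3.40e-09; adjusted p = 0.0513 with an estimated correlation), among them Dkc1 at 1.67 and Utp14a at 1.40. Oxidative phosphorylation genes rose by 0.61, with 57 of 72 positive and 2 over the list alone (adjusted p = 5.39e-09; adjusted p = 0.0513 with an estimated correlation), among them Cox6a1 at 3.12 and Sdhb at 1.52. Proteasome subunits rose by 0.70, with 32 of 38 positive (adjusted p = 1.60e-07; adjusted p = 0.114 with an estimated correlation), among them Psmd13 at 1.85 and Psma7, 2.14-fold higher. Translation factors rose by 0.15, with 28 of 42 positive (adjusted p = 0.00317; adjusted p = 0.291 with an estimated correlation), among them Eif4ebp2 at 1.36 and Eif2s2 at 1.24. Their median was 0.09 without HSC 1, 0.08 without MPP 1 and 0.27 with processed signal. Heat shock genes rose by 0.43, with 16 of 21 positive (adjusted p = 0.0200; adjusted p = 0.397 with an estimated correlation), among them Hsp90aa1 at 0.88 and Cct8 at 0.81. The heat shock call ended without HSC 1 (0.28, adjusted p = 0.151), HSC 2 (0.40, adjusted p = 0.0799) or MPP 3 (0.30, adjusted p = 0.102), in a range from 0.00266 to 0.397. Polycomb subunits rose by 0.44, with 18 of 26 positive and, over the list alone, 1 higher and 1 lower (adjusted p = 0.0343; adjusted p = 0.395 with an estimated correlation). Rbbp4 stood at 1.36 and Pcgf2 at -1.55. The Polycomb call ended without HSC 1 (0.16, adjusted p = 0.351) or MPP 1 (0.42, adjusted p = 0.0702), in a range from 0.0105 to 0.395. The p53 targets rose by 0.40, with 16 of 25 positive and 1 over the list alone (adjusted p = 0.0343; adjusted p = 0.253 with an estimated correlation), among them Pmaip1 at 3.25 and Aen at 1.24. The p53 call ended without HSC 1 (0.20, adjusted p = 0.247), HSC 2 (0.39, adjusted p = 0.125), MPP 1 (0.25, adjusted p = 0.0564) or MPP 3 (0.19, adjusted p = 0.0575), in a range from 0.00943 to 0.258. Their median was 0.24 without MPP 2 and 0.09 without the filter.

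Among other blood cells in the KO channel, granulocyte markers rose by 0.67, with 14 of 19 positive (adjusted p = 0.00875; adjusted p = 0.395 with an estimated correlation), among them Mpo at 3.72 and Ms4a3 at 2.83. Without HSC 1 (0.41, adjusted p = 0.103) or HSC 2 (0.42, adjusted p = 0.0757) they did not pass, in a range from 3.79e-06 to 0.395, and the median was 1.19 without HSC 3. Monocyte markers rose by 0.23, with 9 of 16 positive and 1 over the list alone (adjusted p = 0.0307; adjusted p = 0.210 with an estimated correlation), among them Mpeg1 at 3.95 and Irf8 at 2.37. Without HSC 1 (0.13, adjusted p = 0.105) or HSC 2 (0.20, adjusted p = 0.0686) they did not pass, in a range from 0.0154 to 0.210. Their median was 0.40 without HSC 3, 0.43 without MPP 1 and 0.04 without MPP 3. Basophil markers rose by 1.57, with 9 of 11 positive and 1 over the list alone (adjusted p = 0.0343; adjusted p = 0.573 with an estimated correlation), although Il4 stood at -1.13 beside Ccl3 at 4.98. The basophil call ended without HSC 1 (0.39, adjusted p = 0.420), HSC 2 (1.21, adjusted p = 0.163), MPP 1 (0.90, adjusted p = 0.109) or MPP 3 (1.25, adjusted p = 0.0575), in a range from 1.25e-05 to 0.573, and the median was 2.95 without HSC 3. Megakaryocyte markers fell by 0.67, with 3 of 15 positive and 1 lower over the list alone (adjusted p = 0.00875; adjusted p = 0.221 with an estimated correlation), among them Mmrn1 at -2.94 and Rab27b at -1.03. Without HSC 1 the list did not pass (-0.59, adjusted p = 0.122, in a range from 4.45e-04 to 0.221), and without HSC 2 its median was -1.20.

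With limma 153 features passed in the KO channel, 122 higher and 31 lower in MPPs, each by at least 2-fold, and 3512 had an unadjusted p under 0.05. The groups did not overlap for 19.7%, where chance gives 10%. The count was 93 without HSC 1, 70 without HSC 2, 155 without HSC 3, 67 without MPP 1, 73 without MPP 2 and 58 without MPP 3. Of 32 named genes that passed, 8 passed in all 6 of these fits: Dntt, Drc7, H2-DMb2, Mthfd2, Plau, Rag2, Tmem150b and Tmem156. With the replicate number in the model 37 features passed and with the array row 16. Scaling both channels by the 75th percentile of processed signal moved the median of all features from -0.09 to -0.27 in the WT channel and from -0.09 to -0.16 in the KO channel. The other 12 lists had adjusted p of 0.101 or more and medians from -0.39 to 0.36; median and mean differed in sign for T and NK cell genes. Whether the WT and KO population differences differ from each other is the difference of effects tested above.

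Lists that passed in none of the 6 comparisons had these medians for KO against WT. Interferon response genes had -0.28 in HSCs (adjusted p = 0.604) and -0.25 in MPPs (adjusted p = 0.272), and oxidant defence genes 0.10 in both (adjusted p = 0.604 and 0.614). Unfolded protein and integrated stress response genes had 0.20 and 0.12 (adjusted p = 0.756 and 0.469). Hox genes, classical Polycomb targets, had 0.14 and 0.04 (adjusted p = 0.834 and 0.873), and other developmental transcription factors repressed by Polycomb -0.12 and 0.00 (adjusted p = 0.444 and 0.806). Erythroid genes had 0.12 and 0.39 (adjusted p = 0.776 and 0.105), T and NK cell genes -0.11 and -0.12 (adjusted p = 0.756 and 0.430), sex-linked genes -0.12 and -0.06 (adjusted p = 0.970 and 0.614), and neighbours of Bmi1 on chromosome 2 0.23 and -0.04 (adjusted p = 0.756 and 0.918). With limma 1 of these neighbours passed lower in HSCs when adjusted over the list alone. The sex-linked list joins Xist with Y-linked genes, which a difference in sex would move in opposite directions. Its median and camera test therefore cannot show whether KO and WT samples differed in sex.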

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

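The tests of a fixed dye effect and the splits of the samples were chosen only after the results were seen. The tests of B cell content, handling stress and probe or spot noise were set before they were run, to address patterns in these results. The bounds for B cell content and handling stress were computed from the observed list medians. By camera with a preset correlation the KO effect on B lineage genes differed between the populations, with a median difference of 1.43 (MPP minus HSC), and so did that on basophil, mast cell and eosinophil markers, at -0.96. Neither passed with an estimated correlation (adjusted p = 0.924 for both), and the basophil call also ended without HSC 3, without MPP 3 and with median centring. Spike-in spots, not used here, gave signal in both channels: at least 49.7% and at most 67.7% of 350 E1A spots were well above background, and at least 48.0% and at most 62.6% of 2772 ERCC spots, against at most 1.30% of the 308 negative control spots.

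B lineage genes were higher in the KO channel of MPPs, with a mean of array medians of 1.60. A dye effect fixed to the probes would be alike in both populations, but the MPP array medians exceeded the HSC ones by 1.73 (SE 0.60) on average and each MPP median lay above each HSC one. Other mature B cell genes did not rise in KO MPPs as a set, at -0.28 (SE 0.09), below the 0.80 set as the bound. A small number of mature B cells is not excluded by this, because several of these genes already had a strong signal. Mean log2 levels were 13.97 for Ciita, 13.4 for Cr2 and 13.3 for Cd37, and a few added cells need not move such ratios. Among members with a weaker signal, Fcmr stood at -0.399, H2-Eb1 at -0.39 and Bank1 at 0.16. Pro-B or pre-B cells stay open, since other genes of those cells stood at 0.67 (SE 0.40) around the same bound of 0.80 (camera p = 0.00194, and 0.101 with an estimated correlation; Vpreb2 at 2.95). A shift of KO MPPs toward the B lineage, a few B cells or their precursors that passed the sort and the genotype itself cannot be told apart. No sort purity is given in the sources used here.

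Immediate early genes were higher in the KO channel with array medians of 0.79, 1.88 and -0.34 in HSCs and 1.08, 0.61 and -0.18 in MPPs. A fixed dye effect cannot be told apart from genotype, since the MPP medians differed from the HSC ones by -0.27 (SE 0.74) and no array had the dyes exchanged. Handling or dissociation stress of the KO cells also stays open, as dissociation-induced genes outside the list stood at 0.30 (SE 0.41) around a bound of 0.32. By population they had a median of 0.43 in HSCs (11 of 12 positive, camera p = 0.0312, and 0.422 with an estimated correlation; array medians 0.61, 2.004 and -0.85) and of 0.0053 in MPPs (7 of 12 positive, camera p = 0.909; array medians 0.56, -0.47 and -0.07). A biological difference by genotype was not separated from either.

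Log2 ratios of replicate arrays hardly correlated. Noise of single spots is argued against by repeated spots of the same probe, which correlated within each array at 0.957 to 0.990 over 308 to 348 probes. Different probes of the same gene correlated at only 0.154 to 0.269 over 2757 gene pairs, which is consistent with noise that belongs to single probes. No biological explanation was tested for this pattern.

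Other splits of the arrays were counted for each comparison. For HSCs and for MPPs the 4 ways of assigning the signs, and for the difference and both population comparisons the 10 splits, are too few for a share under 0.05. With the labels as given, 0 features passed in HSCs, in MPPs, in the difference and for the mean effect, and the highest of the other splits was 0 in each. Every split gives at least 0, so the 4 of 4, 4 of 4, 10 of 10 and 32 of 32 that gave as many say nothing about chance. At unadjusted p under 0.05 another split gave more features: 2783 against 2156 in HSCs and 1637 against 1487 in MPPs. In the difference 3449 stood against 1175, and for the mean effect 2991 against 2438. For lists the real count was 1 in HSCs (highest other 3, with 3 of 4 as many), 3 in MPPs (highest other 4, with 3 of 4) and 2 in the difference (highest other 5, with 7 of 10). Between WT populations 122 features and 17 lists passed (highest others 0 and 15, with 1 of 10 as many in each), and between KO populations 153 and 18 (highest others 0 and 18, with 1 and 2 of 10). For the lists of the mean effect chance was not excluded: 5 passed (highest other 6, with 8 of 32 as many).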

How the results depend on the processing

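Array weights and leaving out both arrays of replicate 2 or of replicate 3 were chosen only after the data were seen. Signal over background limits ratios of weak genes: 72.5% to 83.9% of spots were well above background, and a fold against a side that was not is a lower bound. Leaving out an array left 2 or 3 in each population, with limma pooling the spread. Of the values of named genes under other settings 4237 kept direction and side of the threshold, 538 lost the call, 37 gained it and 28 reversed. Only the named genes that passed at the main settings, 26 between WT populations and 32 between KO populations, could lose a call. The others could only reverse or gain one, so the number kept does not measure how stable the calls were. Of list values 425 kept the call, 137 lost it and 1 reversed, and of counts 160 stayed within 1.5 times, 37 fell, 11 rose and 3 correlations moved. Unless stated, the cause was not tested.

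Gene lists depended on the test. In HSCs, MPPs, the difference, the mean effect, WT populations and KO populations, 1, 3, 2, 5, 17 and 18 lists passed with the preset correlation, 0, 0, 0, 0, 0 and 2 with an estimated one and 0, 0, 0, 0, 7 and 10 with fry. The immediate early genes (0.53 in HSCs, 0.67 for the mean effect), the B lineage (1.48 in MPPs, 1.43 in the difference) and ribosome biogenesis (0.26 for the mean effect) lost their calls under both of these tests, which leave medians unchanged.

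Median centring left the median log2 ratio of all features at 0.29 in HSCs and 0.26 in MPPs. It gave 303 features for the mean effect (299 higher, 4 lower) against 0, 7 lists in HSCs, 8 in MPPs, 1 in the difference and 10 for the mean effect, and an r of 0.278 against 0.111 between HSC and MPP effects. It turned the Hspa4 mean effect to 0.10 and the computed Cdkn2b difference to 0.082. Neither size nor sign of that difference is an estimate of an effect, as the only Cdkn2b HSC signal well above background was in KO on HSC 1. The Agilent log ratio gave 2 lists in HSCs. With it and with the deposited series values, which are the same, the Cdkn2b difference again changed sign and the Hspa4 mean effect was 0.42. As a mean of probes Pdzk1ip1 was 0.042 in HSCs, Phc2 -0.050 in MPPs and Ccne1 -0.37 for the mean effect. Array weights turned Bmi1 in MPPs to -0.025.

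Between WT populations 122 features passed, against 51 without the filter, 281 with the separate-channel model, 0 with the replicate block and 0 with the array row as a term. Between KO populations 153 passed, against 37 with the replicate block and 16 with the array row. The array row turned the Prg2 difference to 0.22 and Bmi1 between WT populations to -0.016. The replicate numbers were not treated as pairing, because not every pair exceeded 0.1, but samples with the same number were not shown to be independent: their correlations were all positive within a channel (0.0375 to 0.156 in WT, 0.00281 to 0.0947 in KO), and Xist, S100a8, S100a9 and Ngp differed by number in both populations. Whether they share a source is left open. The block correlation of the ratios was -0.0849, pairs with the same number exceeded 0.1 for 0 of 3 in the ratio, 2 of 3 in the WT channel and 0 of 3 in the KO channel, and 1, 5 and 3 of 6 samples matched best with their own number. With the block as a fixed term 100 of 154 named gene values kept side and direction, 53 lost the call and 1 gained it. Only named genes called without the block, 26 between WT populations and 32 between KO populations, could lose a call. As a random term the block was run only on the KO against WT comparisons, where no gene was called and none could lose a call.

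Leaving out arrays gave these ranges, of which those of Cdkn2b rest on weak signal, as its only HSC signal well above background was in KO on HSC 1. Counts of features ran from 0 (without MPP 3) to 121 (without MPP 2) between WT populations and from 0 (without replicate 3) to 155 (without HSC 3) between KO populations. Lists ran from 1 to 2 in HSCs, 4 to 7 in MPPs, 1 to 5 in the difference, 2 to 7 for the mean effect and 11 to 21 between KO populations. The immediate early median ran from 0.30 to 1.32 in HSCs and from 0.45 to 1.29 for the mean effect, the granulocyte median between WT populations from -0.066 to 1.17 and the r between HSC and MPP effects from 0.0591 to 0.131. Computed values of Cdkn2b ran from -0.26 (without HSC 1) to 1.34 (without HSC 3) in HSCs. They ran from -0.78 (without replicate 2) to 0.88 (without HSC 1) in the difference. Between KO populations they ran from -0.75 (without replicate 2) to 1.45 (without HSC 1). Without HSC 1 no HSC signal of Cdkn2b was well above background in either channel. The values of the difference are therefore not estimates of an effect and only show how the fit moved. Bmi1 ran from -0.23 (without MPP 3) to 0.35 (without MPP 2) in MPPs and from -0.016 (without replicate 2) to 0.92 (without replicate 3) between WT populations. Cdkn2a ran from -0.20 (without HSC 1) to 0.59 (without HSC 3) for the mean effect and from -1.40 (without HSC 1) to 0.14 (without HSC 3) between WT populations.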

Other observations

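The test of fetal-type genes and the genes and gene classes below were chosen only after the data were seen. Immunoglobulin variable region features, many named only by accession, stood out among those higher in MPPs. Of 72 kappa variable features 10 passed higher in the WT channel (median log2 difference of the class 3.29) and 15 in the KO channel (2.67). Of 41 heavy chain features 10 passed in WT (4.42) and 17 in KO (4.16). Among 10 MHC class II features 1 passed in WT (1.14) and 2 in KO (1.47). Probes for members of the same gene family can share sequence, so these features are not independent. The classes were chosen because they stood out among the calls, so a test for an excess among the same calls would only restate that.

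Calls of the WT and KO population comparisons overlapped: 36 features passed higher in MPPs in both channels where independent lists give 0.440, and 4 passed lower where they give 0.0181, with 0 in opposite directions. The channels come from the same 6 arrays and spots, so the lists are not independent and the excess does not measure a shared effect. The shared genes with names included Flt3, Dntt, Rag2, Cd180, Cebpa and Bex6 on the higher side, and Clca3a2, Tgm2 and Sult1a1 on the lower. Of the 30 lists 15 passed in both population comparisons, 2 in WT alone, 3 in KO alone and 10 in neither.

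Levels of some genes differed between replicate numbers in both genotypes and both populations. Xist, the RNA of the inactive X chromosome, had log2 levels from 5.88 to 6.73 in all 4 samples of replicate 2 and from 11.5 to 14.2 in the others. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were well above background in all samples, and none of them set replicate 2 apart in both channels. Ddx3y (10.04 and 11.3 against 7.97 to 9.34) and Uty (7.47 and 8.89 against 6.21 to 7.13) were higher there in WT alone, and in KO alone Kdm5d was higher (10.73 and 12.3 against 8.29 to 10.2) and Eif2s3y lower (9.30 and 9.70 against 9.85 to 12.02). The neutrophil genes S100a8, S100a9 and Ngp had levels of 12.16 to 13.01, 11.3 to 13.1 and 12.1 to 14.1 in the 4 samples of replicate 3, against 5.81 to 10.6, 6.01 to 10.3 and 6.29 to 10.5 in the others. Of other neutrophil genes, Lcn2 did not set replicate 3 apart. It was 9.15 and 10.23 there in WT against 9.36 to 10.19 in the others, and 10.87 and 11.003 in KO against 10.77 to 11.7. Camp was higher in replicate 3 in KO (9.10 and 9.82 against 8.51 to 8.98), while its WT levels overlapped (7.49 and 7.95 against 6.94 to 7.57). Granulocyte list medians in the KO channel were 8.44, 8.51 and 11.1 in HSCs and 10.0, 10.2 and 10.9 in MPPs.

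Lin28b was higher in the KO channel of all 6 arrays by its log2 ratio, with a WT signal not well above background on 5 of 6. A dye effect fixed to its probe cannot be told apart from genotype, since no array had the dyes exchanged. Another candidate explanation is a wider fetal-type programme in KO cells. Among 10 other fetal-type genes measured the median of the mean effect was 0.27 (camera p = 0.468, and 0.716 with an estimated correlation), which leaves it open.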
